A study of Xenopus laevis with 12 samples.

How the data were processed

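Whole *Xenopus laevis* embryos were measured on 12 arrays, each with biotin-labelled cRNA made from 100 ng of total RNA with a 3' IVT kit, per the labels' protocols. Embryos came from in vitro fertilization and were kept at 22 °C. Morpholino oligonucleotides (MOs, antisense oligonucleotides that block translation or splicing of an RNA) were injected into the animal pole of every blastomere at the 4-cell stage. The control oligonucleotide, CoMO, and Fam46a-MO1 were given at 10 ng per cell, and Fam46a-MO2 and Fam46a-MO3 were given together at 7 ng each per cell. The groups are the 3 injections at each of the 2 stages, with 2 biological replicates per group. The labels do not say which oligonucleotide blocks translation and which blocks splicing, nor how the stages were judged.

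The authors deposited 1 table of log values per probe set, made with RMA per the submitters' processing notes, with no version given. RMA works on the log2 scale, and the deposited values were taken as log2, although no source used here states the base. The deposited values were also centred: for all 32635 probe sets the median of the 6 arrays of each stage lies within 1e-06 of 0. No header or label records that step. Centring removed the level of each probe set and its difference between the stages, and left the differences between arrays of the same stage. The array medians lie between -0.0106 and 0.0120. The number of arrays limits the precision, and no scanner files were among the files used.

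The 96 control probe sets were left out, which left 32539 tested. A table of the platform's annotation names 1 gene for 15495 of them, several for 279 and none for 16765, which are left unnamed here. Symbols were checked against a gene table of the assembly Xenopus_laevis_v10.1, which matched 15384 of the probe sets with 1 gene and updated 2 symbols. No coordinates are given, since the sources used here do not name a build for the array. The suffixes .L and .S mark the paired copies of a gene on the long and short subgenome. Probe sets can hybridise to both copies, so a value of 1 copy is not certain to exclude the other.

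Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 12 arrays with 1 coefficient per group, followed by eBayes and two-sided moderated tests with Benjamini-Hochberg adjustment over all probe sets of a contrast. A probe set was called at an adjusted p under 0.05. Errors after ± are moderated standard errors of the log2 difference, with 2 arrays per group. The contrasts were each reagent against CoMO within a stage, the mean of both reagents against CoMO, the difference between the reagents, and the change of each reagent's effect between the stages. The replicate numbers pair the samples: the deviations of same-numbered arrays from their group means correlated at 0.821 to 0.864 in the 3 pairs of groups of each stage, and at -0.0164 to 0.0244 between the stages. The labels name biological replicates and do not say what a number shares. A fit with the replicate number within each stage as a block was therefore made as well, and its values stand beside those without the block where they differ in the call or by more than 1.5 times. The median residual standard deviation was 0.175 on 6 degrees of freedom without the block and 0.104 on 4 with it.

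Before the data were examined, the tests, the gene lists, the rule for naming genes and most alternatives were fixed. The rule names the genes of the fam46 family, up to 12 genes per direction with the largest mean change among probe sets called with the same sign in both reagents, the 4 largest changes per direction of each other contrast, and from each list up to 4 called members and up to 2 members against its median. Where fewer than 5 probe sets qualified in a direction, those called for the mean of both reagents filled up. It was applied to the fit without the block and to the fit with it. Lists were tested with camera at its preset correlation of 0.01 on the mean over the probe sets of each of 11303 gene symbols, with adjustment over the lists and contrasts, and again with the correlation estimated from the residuals and with fry. Values of list members are these means, so they can differ from those of a single probe set. Several genes stand in more than 1 list.

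Some planned steps need the level of a probe set and were not run: the contrast of CoMO embryos between the stages, filters at a log2 value of 5 or 7, the variance trend on the mean, and the choice of the probe set with the highest mean. In their place the power-of-2 interval that held the lowest array of a stage before centring was recovered from the rounding of the deposited single-precision numbers. On 20000 simulated values the interval was too high for 4.6% and too low or missing for 0.05%, and from only 4 arrays, as for the classes of rising and falling probe sets, too high for 9.67% and too low or missing for 0.03%. In the data, 6 of 6 TrpnX control probe sets at each stage fell below 4, and of the 6 spiked BioC, BioDn and CreX control probe sets 6 at stage 8 and 5 at stage 10.5 stood at 8 or above. A group whose lowest array had a lower bound below 4 was read as reaching the range of the negative controls. At least 1 group did so for 27 of the 75 named probe sets at stage 8 and 10 at stage 10.5, and a change against such a group is a lower bound of its size.

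The scripts were tested on simulated data shaped like MO1 against CoMO at stage 10.5. Of 100 probe sets changed by a log2 difference of 1, the fit without the block recovered 40, and of 100 changed by 2 it recovered 84, with 0 unchanged probe sets called. The fit with the block recovered 100 and 100, with 13 unchanged probe sets called among 32539. Camera called 2 of 2 shifted lists and 0 of 20 unshifted ones among 11303 genes. Those lists were random draws of genes, so false calls of lists whose genes move together were not tested. Groups of 2 arrays are too small for a search for outlying arrays within a group and for counts over other splits of the samples. Calculations outside limma used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used matplotlib 3.10.9.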

Results

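Gene expression was profiled in whole frog embryos in which fam46a had been targeted, on 12 arrays. Embryos were collected at stage 8, a blastula stage, and at stage 10.5, the start of gastrulation. At each stage 2 arrays held embryos injected with CoMO, 2 held embryos injected with Fam46a-MO1 (MO1) and 2 held embryos injected with Fam46a-MO2 and Fam46a-MO3 together (MO2+MO3). The stated purpose was to find the genes affected by depletion of fam46a, which codes for a member of the FAM46 (TENT5) family of poly(A) polymerases. Values are log2 differences between arrays of the same stage, with no level of their own, so all changes below are against CoMO of the same stage unless another group is named.

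The targeted gene is listed as tent5a.L (gene 100158383) and has 2 probe sets. On the first, the centred values of CoMO, MO1 and MO2+MO3 at stage 8 were 0.12 ± 0.37, -0.04 ± 0.26 and 0.21 ± 0.73, and at stage 10.5 they were -0.14 ± 0.40, -0.12 ± 0.01 and 0.25 ± 0.19 (mean ± SD, n = 2). On the second they were 0.09 ± 0.17, 0.07 ± 0.75 and -0.04 ± 0.09 at stage 8, and 0.02 ± 0.10, -0.08 ± 0.08 and 0.08 ± 0.08 at stage 10.5. Neither probe set was called in either reagent at either stage. The related tent5b.S was not called either, with changes at stage 10.5 over its 2 probe sets of 0.07 ± 0.34 in MO1 and -0.02 ± 0.34 in MO2+MO3. An oligonucleotide that blocks translation leaves the level of its RNA open, so these probe sets check neither the labels nor the depletion. At stage 8 both probe sets of tent5a.L lay near the negative controls, with recovered median levels of 2.3 to 4.3 and 2.5 to 4.5, so a fall there could have gone unseen.

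At stage 8 few genes were called against CoMO. In MO1 embryos dbn1.S (gene 494829), which codes for the actin-binding protein drebrin, fell, with a change of -2.10 ± 0.12 (adjusted p = 0.0032), while its change in MO2+MO3 was 0.10 ± 0.12. It accounts for both probe sets called in MO1, and 0 were called in MO2+MO3. Without the block and without either CoMO array of stage 8 the count in MO1 was 0. With the replicate block, rpn2.S (gene 379348), a subunit of the oligosaccharyltransferase of the endoplasmic reticulum, rose in both reagents, by 1.93 in MO1 and 2.50 in MO2+MO3 (adjusted p = 0.00085 and 0.0003, against 0.31 and 0.16 without the block). So did uqcrc1.L, a subunit of respiratory complex III, with 1.57 and 1.44 (0.0034 and 0.013 with the block), cct4.S, a chaperonin subunit, with 1.15 and 1.09 (0.014 and 0.023), and pomp.S, a proteasome maturation factor, with 0.78 and 0.85 (0.0099 and 0.013), while its other probe set had changes of -0.13 and -0.11. With the block, the count of probe sets called in both reagents, 4, was 1 on the 6 arrays of stage 8 alone, without CoMO replicate 2 and without MO2+MO3 replicate 2, so at least 3 of these shared rises did not stand in each of those fits, and it was 2 without MO1 replicate 1.

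Other genes at stage 8 were called with the block for 1 reagent. In MO1, the Toll-like receptor adaptor myd88.S rose by 1.21 ± 0.12 (adjusted p = 0.0099), and rpp25l.S, fnta.S and gpr89b.L fell, with changes of -1.87, -1.77 and -1.48 (0.0043, 0.0014 and 0.0054). In MO2+MO3, chchd5.L, nmd3.L, gins4.L and zcchc9.L fell, with changes of -1.42, -1.41, -1.21 and -1.09 (0.034, 0.012, 0.005 and 0.023). The values of chchd5.L and nmd3.L are from 1 probe set each: the other of chchd5.L had a change of 0.21, for a mean of -0.60, and the 3 of nmd3.L had a mean of -0.96, with -0.09 on the highest. For the mean of both reagents, the ligand wnt8a.L fell by 0.61 ± 0.07 (0.038), and sirt3.2.L and cyc1.S fell, with changes of -0.76 and -0.72 (0.038 each). For sirt3.2.L the changes in the 2 reagents were -1.38 and -0.13. All of these p-values are from the fit with the block, and without it the same genes had adjusted p from 0.12 to 1. With the block on only the 6 arrays of stage 8, and with it on the arrays without CoMO replicate 2, 0 probe sets were called lower in MO2+MO3 or for the mean, so none of the falls named for these stood in those fits. At stage 8 nmd3.L and wnt8a.L had arrays at a recovered level below 4, where the negative controls lie, so the sizes of any falls are lower bounds. The lowest CoMO array lay between 2.2 and 3.2 for nmd3.L and between 2.7 and 4.7 for wnt8a.L. It was not shown to lie above that range, so a fall from a detected level is not shown for either gene. Between the reagents, selenos.S was higher in MO1 by 2.06 with the block (0.024, against 0.29 without it), and rrs1.S was lower in MO1, with changes against CoMO of -1.25 in MO1 and 0.75 in MO2+MO3 (adjusted p of the difference 0.011 with the block and 1 without it).

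In counts, the limma fit without the block called 2 probe sets in MO1 at stage 8, both lower, 0 in MO2+MO3, 0 for the mean of both reagents, 0 in both reagents and 2 between the reagents. Unadjusted p under 0.05 were found for 628, 763 and 664 probe sets in MO1, MO2+MO3 and their mean without the block and for 2666, 3544 and 2993 with it, where chance gives 1627. The counts without the block lie below chance, because the difference between replicates that the groups of a stage share stays in its residual. Its tests at stage 8 are therefore conservative, and its few calls do not show that few genes differed. With the block, 40 were called in MO1 (9 higher, 31 lower), 46 in MO2+MO3 (6 higher, 40 lower), 17 for the mean, 124 between the reagents and 4 in both reagents, all higher. These block counts were unstable: without CoMO replicate 2 they were 5 in MO1, 1 in MO2+MO3 and 1 for the mean, without CoMO replicate 1 they were 13, 4 and 4, and on the 6 arrays of stage 8 alone they were 14, 1 and 1. Without MO1 replicate 1 the count in MO1 was 23, and without MO2+MO3 replicate 2 that in MO2+MO3 was 3 and that for the mean 2. Without MO1 replicate 1 or 2 or MO2+MO3 replicate 1 the mean had 10, 32 or 27. Simulated unchanged groups sharing the CoMO arrays gave 0.02 calls in both reagents on average, with a maximum of 1, and independent lists of these sizes share 0.00166 higher and 0.0381 lower probe sets. Part of the overlap may come from the shared CoMO arrays, which are too few to split. The simulations held no changed probe sets, so hardly any could be called and they do not measure that part.

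At stage 10.5 some epidermal genes were lower, 6 of the 41 listed in MO1 and 4 in MO2+MO3, while the list's medians were -0.06 and -0.13 and its calls did not all hold, as given below. The epidermal keratin krt12.4.L (gene 379535) fell, with changes of -2.80 ± 0.13 in MO1 and -2.43 ± 0.13 in MO2+MO3 (adjusted p = 0.0004 and 0.0018). Its recovered median level at stage 10.5, between 1.5 and 2.5, lies in the range of the negative controls, so these sizes are lower bounds, and its lowest CoMO array, between 3.8 and 4.8, was not shown to lie above that range. The homeobox genes dlx3.L and dlx3.S, which act in non-neural ectoderm, fell, with changes of -1.54 ± 0.13 and -1.27 ± 0.11 in MO1 (0.0031 each) and -1.53 ± 0.13 and -1.35 ± 0.11 in MO2+MO3 (0.0074 and 0.0071). The value of dlx3.L is from 1 of 3 probe sets, whose mean changes were -0.88 and -1.24, with 0.40 in MO1 and -0.73 in MO2+MO3 on the highest. A second keratin, krt70.L, fell by 2.22 ± 0.37 in MO1 (0.038) and had a change of -1.88 ± 0.37 in MO2+MO3 (0.067, and 0.00079 with the block). With the block krt12.5.S, at -3.50 and -2.31, and krt12.4.S, at -2.73 and -1.99, were also called in both reagents (adjusted p at most 0.00025, against 0.077 to 0.35 without it). Arrays with a targeting reagent also reached levels below 4 for these 2 keratins.

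**Figure D1:**
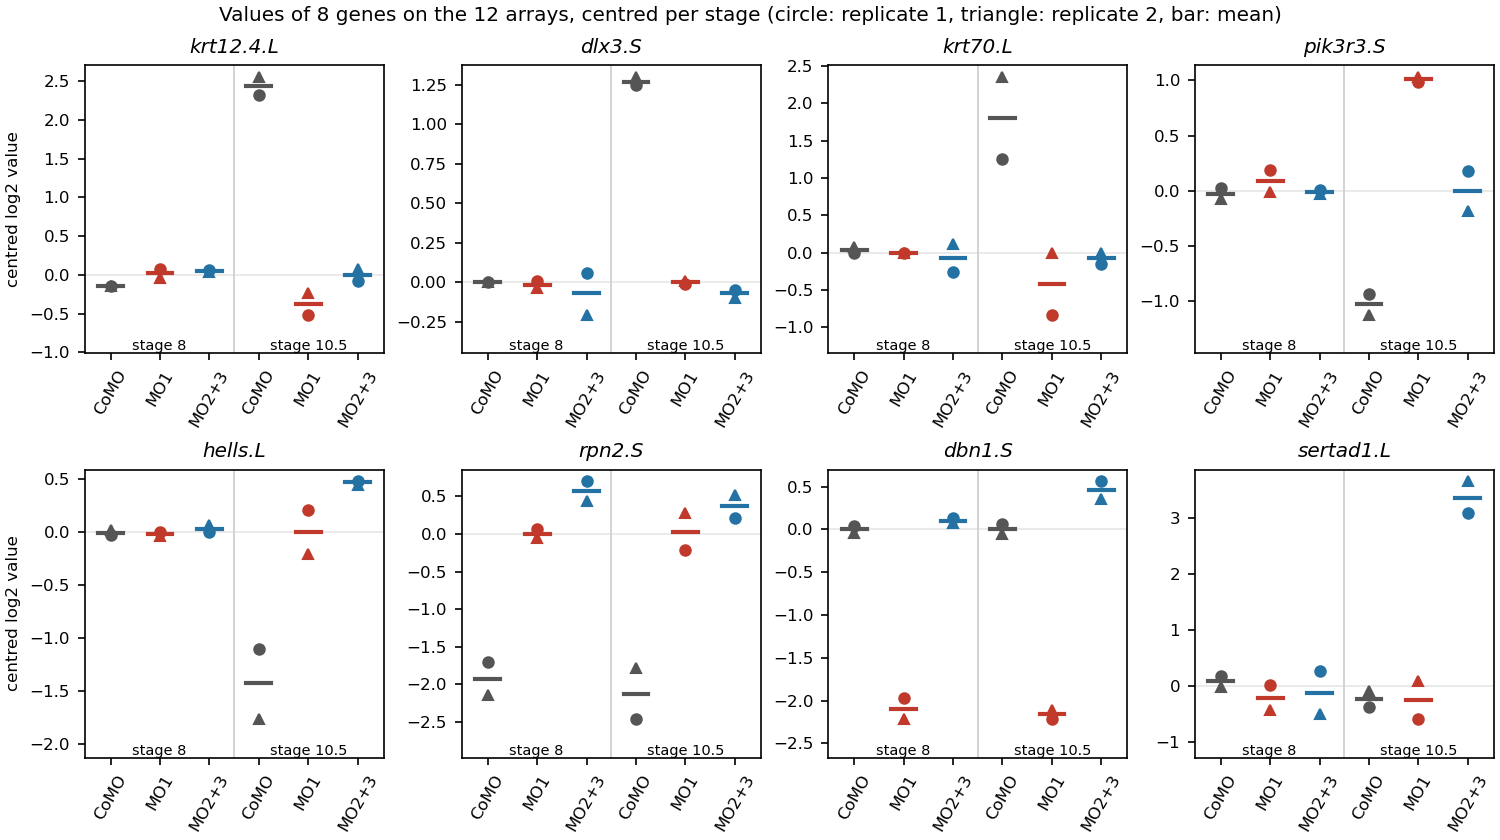
Centred log2 values of 8 genes (y axis) on the 12 arrays, by injected group and stage (x axis), with circles for replicate 1, triangles for replicate 2 and bars for group means (n = 2). For *krt12.4.L* and *dlx3.S* both CoMO arrays of stage 10.5 lie above all 4 arrays of the targeting reagents, and *dbn1.S* is low in MO1 at both stages, with changes of -2.10 and -2.16 on the probe set shown.

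Other genes fell with both reagents at stage 10.5. Both copies of loxl1, which codes for an enzyme that cross-links collagen and elastin, had mean changes over the reagents of -1.46 (loxl1.S) and -1.30 (loxl1.L). The remaining named genes were acy3.L at -1.43, the purine nucleoside phosphorylase pnp.L at -1.31, post.L at -1.25, trim29.S at -0.99 and trim29.L at -0.79, with adjusted p for the mean between 0.004 and 0.024. With the block the lower genes also included the muscle regulator myf5.L at -1.72 ± 0.11, the zinc transporter slc30a8.L at -1.78 ± 0.14, the mesodermal T-box gene tbxt.2.S at -1.67 ± 0.20, gnb3.L at -1.59, znf451.L at -1.57 and the secreted antagonist cer1.S at -1.52 ± 0.14 (adjusted p for the mean 0.00011 to 0.0012, against 0.034 to 0.32 without it). Over its 3 probe sets znf451.L had a mean of -0.72, with 0.79 on the highest, and post.L had a mean of -0.84 over 7. For acy3.L, cer1.S and tbxt.2.S the lowest array with a targeting reagent may lie below a level of 4, so their falls are lower bounds, and for acy3.L and tbxt.2.S the lowest CoMO array, between 3.5 and 5.5, was not shown to lie above it either.

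The gene with the largest rise in both reagents was rpn2.S, with 2.16 ± 0.27 in MO1 and 2.49 ± 0.27 in MO2+MO3 (adjusted p = 0.015 and 0.012). Next came hells.L, a chromatin remodelling helicase, with 1.43 ± 0.21 and 1.90 ± 0.21 (0.029 and 0.014), and abhd18.L with 1.68 and 1.48. Both copies of pik3r3, a regulatory subunit of phosphoinositide 3-kinase, rose, pik3r3.S by 2.04 ± 0.14 and 1.03 ± 0.14 (0.0014 and 0.024) and pik3r3.L by 1.93 and 0.80. Mean changes of mapkbp1.L, coq10a.L, the casein kinase gene tptep2-csnk1e.L, rell1.S, gramd2b.S, nipal4.S and the focal adhesion kinase gene ptk2.S were 1.36, 1.36, 1.35, 1.31, 1.28, 1.23 and 1.19 (adjusted p 0.004 to 0.028). With the block sbk1l.L (1.77), tmem181.L (1.62), the repressor gene bcl6.L (1.53), uqcrc1.L (1.48), tmem106b.S (1.47), tpcn2.L (1.40), rspry1.S (1.39) and oaf.S (1.38) joined them, with adjusted p for the mean between 0.0001 and 0.00068, against 0.045 to 0.44 without it. In bcl6.L the CoMO arrays reached the range of the negative controls, so its rise is a lower bound, and the lowest arrays of MO1 and MO2+MO3, from 3.2 and 3.5 upward, were not shown to lie above it. Several values are from 1 probe set of a gene and differ from the mean over all of them, which was 0.78 in MO1 and 1.29 in MO2+MO3 for the 3 of hells.L and, for the mean of both reagents, 0.26 for the 11 of sbk1l.L, 0.67 for the 7 of tmem181.L, 0.56 for the 3 of coq10a.L and 0.39 for the 3 of nipal4.S.

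Some changes at stage 10.5 were called without the block in 1 reagent, and several of them in the other with the block. In MO1 the intermediate filament gene prph.L fell by 2.90 ± 0.39 (adjusted p = 0.02), dbn1.S, on another probe set than at stage 8, fell, with a change of -2.20 ± 0.14 (0.0011), and rell1.L rose by 1.97 ± 0.16 (0.0023). With the block hprt1.L, a purine salvage enzyme, rose by 1.96 ± 0.10 (3.9e-05, against 0.31 without it). In MO2+MO3 sertad1.L (gene 444534) rose by 3.60 ± 0.34 (0.0083), a lower bound, since its CoMO arrays reached the range of the negative controls, tmem181.L by 2.68 ± 0.34 (0.018) and cpeb1.L, whose product binds the cytoplasmic polyadenylation element of maternal mRNAs, by 2.16 ± 0.29 (0.02). The RNA-binding protein gene caprin2.L fell by 1.56 ± 0.25 (0.037), and rcan1.L, which codes for an inhibitor of calcineurin, fell, with a change of -1.50 ± 0.09 (0.0023). With the block, MO2+MO3 had changes of -0.69 for prph.L (0.015), 0.39 for dbn1.S (0.044, of the opposite sign) and 0.52 for hprt1.L (0.0084), and MO1 had changes of 0.57 for tmem181.L (0.041) and 0.46 for cpeb1.L (0.0097). The mean changes over the 7 probe sets of tmem181.L were 0.20 in MO1 and 1.14 in MO2+MO3. For rell1.L in MO2+MO3 and sertad1.L and caprin2.L in MO1 the changes were 0.32, -0.02 and 0.33 (0.068, 0.95 and 0.35 with the block).

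At stage 10.5, 298 probe sets were called in MO1 (144 higher, 154 lower), 295 in MO2+MO3 (183 higher, 112 lower) and 324 for the mean of both (173 higher, 151 lower). With the block the counts were 5280 (2758 higher, 2522 lower), 5464 (2935 higher, 2529 lower) and 6223, of which 485, 438 and 318 passed a 2-fold change. The block fit called 100% of its probe sets with the same sign in both replicate pairs. A call from 2 pairs nearly requires this, so it gives no separate support. Both reagents shared 70 calls of the same sign (40 higher, 30 lower), and 2615 with the block (1428 higher, 1187 lower), with 1 and 78 calls of opposite sign. Simulated unchanged groups sharing the CoMO arrays gave 0 in either fit, and independent lists of the observed sizes share 0.81 higher and 0.53 lower without the block, and 249 and 196 with it. Part of the excess may come from the shared CoMO arrays. The simulations do not measure that part, because they held no changed probe sets and hardly any could be called. Leaving out any 1 of the 4 arrays of a contrast without the block gave 38 to 102 calls in MO1, 2 to 45 in MO2+MO3, 4 to 202 for the mean and 1 to 22 in both, and with it 2037 to 2676 in MO1 and 2183 to 2849 in MO2+MO3, and a fit to the 6 arrays of stage 10.5 alone without the block called 0.

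Of 41 epidermal and preplacodal genes, 6 fell and 0 rose in MO1 at stage 10.5, and 4 fell and 0 rose in MO2+MO3. With the block 18 fell and 3 rose in MO1, and 12 fell and 2 rose in MO2+MO3. Adjusted over the list alone without it, 13 fell and 1 rose in MO1, and 7 fell and 0 rose in MO2+MO3. The median changes were -0.06 and -0.13 and the means -0.49 and -0.36. Camera gave adjusted p of 1.6e-07 and 0.00033. With an estimated correlation the MO1 call held (adjusted p = 0.03) and the MO2+MO3 call was lost (adjusted p = 0.095), and with the block and an estimated correlation both were lost (adjusted p = 0.42 each). The estimate was -0.004 without the block, below the preset 0.01, so a higher correlation does not account for the larger p-values. Calls of other lists lost with an estimated correlation can therefore not be credited to correlation between their genes alone. Fry, which asks whether the list's genes move one way, gave 0.00043 and 0.0019. It was the one list called with fry in either reagent.

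Mesoderm genes were also lower at stage 10.5, with medians over 40 genes of -0.31 in MO1 and -0.23 in MO2+MO3 (camera adjusted p = 2e-05 and 0.0023). With an estimated correlation both calls were lost (adjusted p = 0.2 and 0.24). With the block 17 members fell and 0 rose in MO1, and 16 fell and 1 rose in MO2+MO3, among them myf5.L, foxc1.L at -1.33 and -1.29, and myod1.S at -1.38 and -1.09, and without it 0 were called. The list of BMP targets and ventral genes, over 32 genes, had medians of -0.38 and -0.27 (9.4e-05 and 0.0026; with an estimated correlation adjusted p = 0.24 each). Its members ventx1.1.S, at -0.74 ± 0.10 in MO1, and evx1.L, at -1.18 ± 0.20 in MO2+MO3, fell without the block (0.018 and 0.04), and adjusted over the list alone 5 fell and 1 rose in MO1, and 2 fell and 2 rose in MO2+MO3. With the block 10 fell and 2 rose in MO1, and 9 fell and 2 rose in MO2+MO3. Wnt targets, over 33 genes, had medians of -0.25 and -0.16 (0.001 and 0.0097; with an estimated correlation adjusted p = 0.24 and 0.35). Their block calls, 12 lower and 2 higher in MO1 and 10 lower and 1 higher in MO2+MO3, included cdx4.L at -1.13 and msgn1.L at -1.04.

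Several further lists were called lower in MO1 and not in MO2+MO3 at stage 10.5 without the block. Organizer genes had a median of -0.34 over 30 genes (camera adjusted p = 9.2e-05; with an estimated correlation adjusted p = 0.24), with crx.S at -1.03 ± 0.16 (0.028) and, with the block, frzb.L at -1.50 and foxa2.L at -1.18. Neural ectoderm genes had a median of -0.15 over 33 genes (0.00022; with an estimated correlation adjusted p = 0.24). In that list meis3.S fell by 0.79 ± 0.13 (0.032) and foxd4l1.2.L rose by 1.43 ± 0.12 (0.0017), and with the block sox2.L, a neural progenitor gene, fell by 1.24. FGF targets (median -0.15 over 29 genes, 8e-04), early zygotic genes (-0.13 over 37, 0.0015) and endoderm genes (-0.28 over 33, 0.028) followed, with adjusted p of 0.2, 0.24 and 0.48 with an estimated correlation. Genes of endoplasmic reticulum chaperones and the unfolded protein response had a median of -0.06 over 37 genes (0.024, and 0.24 with an estimated correlation), and that call was lost with the block (0.055). Their estimated correlation, 0.0077, was also below the preset. With the block the calls of members, lower and higher, were 10 and 1 of the organizer list in MO1 and 6 and 2 in MO2+MO3, 10 and 1, and 4 and 3, of the neural list, 9 and 1, and 3 and 0, of FGF targets, 10 and 2, and 8 and 4, of early zygotic genes, and 11 and 0, and 10 and 0, of endoderm genes. In MO2+MO3 the 6 lists just given had camera adjusted p from 0.079 to 0.98, although with the block endoderm genes were called (0.022, against 0.21, and 0.71 with the block and an estimated correlation). Whether the lists differed between the reagents was not tested.

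Maternal and germ plasm genes were higher at stage 10.5, with medians over 42 genes of 0.11 and 0.05 (camera adjusted p = 0.027 and 0.0024; with an estimated correlation adjusted p = 0.54 and 0.42). With the block the MO1 call was lost (0.051). In MO1 npm2.S, an egg histone chaperone, rose by 0.97 ± 0.16 and the germ plasm gene sybu.S by 0.67 ± 0.11 (0.031 and 0.034), and in MO2+MO3 cpeb1.L rose. With the block 11 rose and 2 fell in MO1, and 8 rose and 2 fell in MO2+MO3, among them btg4.L, an adaptor in the clearance of maternal mRNA, at 1.19 and 1.08. Ribosomal protein genes were lower, with medians over 86 genes of -0.11 and -0.17 (0.0042 and 0.0015). With an estimated correlation of 0.61 between them both calls were lost (adjusted p = 0.82 and 0.77), and without CoMO replicate 2 the median in MO1 was 0.04. Of its members 4 and 5 fell and 0 rose with the block.

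The lists of the secretory pathway, of poly(A) tails, of BMP and TGF-beta components, of the cell cycle and of the p53 response were called with camera in neither fit at stage 10.5, while single members were. Of 56 genes of the secretory pathway machinery 1, rpn2.S, was called in each reagent, and the list had medians of -0.07 and -0.05 (camera adjusted p = 0.21 and 0.42). Of 54 genes of poly(A) tail control and mRNA decay, the poly(A)-specific ribonuclease gene parn.L rose by 0.74 ± 0.12 in MO1 and 0.94 ± 0.12 in MO2+MO3 (0.03 and 0.012), and cpeb1.L rose in MO2+MO3. That list had medians of -0.03 and -0.02 (0.98 and 0.87). Components of the BMP and TGF-beta pathways had medians of 0.04 and 0.02 over 40 genes (0.6 and 0.42), and acvr1b.S rose by 0.71 ± 0.12 in MO1 (0.031). Cell cycle genes had medians of 0.02 and 0.01 over 71 genes (0.98 and 0.86), and mcm6.2.L fell by 0.97 ± 0.16 in MO1 (0.031). Genes of the p53 response and morpholino stress had medians of -0.08 and 0.04 over 29 genes (0.38 and 0.55), with 0 calls without the block and 4 higher and 4 lower with it in MO1, and 1 and 1 in MO2+MO3. With the block 5 members of the secretory list rose and 10 fell in MO1, and 2 rose and 7 fell in MO2+MO3. For the poly(A) list these counts were 11 and 7 in MO1 and 9 and 8 in MO2+MO3, for BMP and TGF-beta components 7 and 2, and 6 and 2, and for the cell cycle 16 and 12, and 11 and 9. Fry's test for members that move in either direction, without the block and not adjusted, gave p of 2.3e-05 and 1.7e-05 for the secretory list, 0.002 and 0.00013 for the poly(A) list, 0.09 and 0.35 for BMP and TGF-beta components, 0.015 and 0.2 for the cell cycle and 0.17 and 0.39 for the p53 list.

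**Figure D2:**
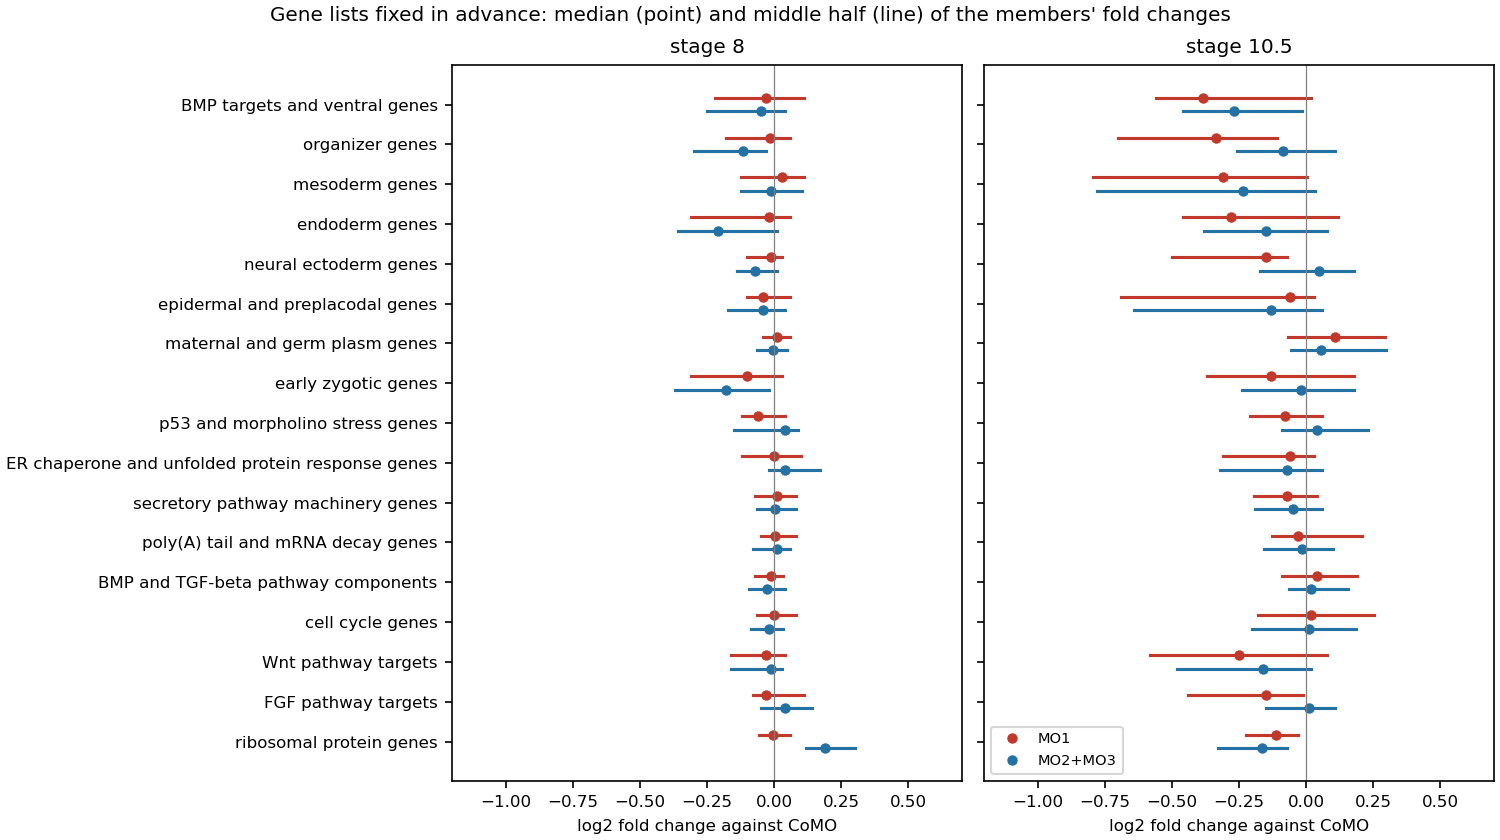
Median (point) and span from the 25th to the 75th percentile of the members (line) of the log2 change against CoMO (x axis) for 17 gene lists (y axis), at stage 8 and stage 10.5, with MO1 in red and MO2+MO3 in blue. At stage 10.5 the medians of BMP targets and ventral genes, -0.38 and -0.27, lie farthest below 0 in both reagents, and the lines of the epidermal list reach far below its medians of -0.06 and -0.13.

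At stage 8 lists fixed in advance shifted by small amounts. Early zygotic genes had medians of -0.10 in MO1 and -0.18 in MO2+MO3 (camera adjusted p = 0.00064 and 0.00012), and endoderm genes had medians of -0.02 and -0.21 (0.0048 and 0.00049). Wnt targets in MO1 had a median of -0.03 (0.042), and in MO2+MO3 BMP targets and ventral genes (-0.05) and organizer genes (-0.11) were called lower (0.0024 and 0.0029) and ribosomal protein genes (0.19) higher (3.1e-09). With an estimated correlation 0 of these 8 calls held (adjusted p = 0.24 to 0.54), and fry called 0. In these lists 0 members were called without the block. Recovered levels were not judged for the lists as a whole. Some named members, such as krt12.4.L of the early zygotic list and cer1.S of the organizer list, lay in the range of the negative controls at stage 8. The small shifts may therefore include members without detected RNA. The remaining lists at stage 8 had camera adjusted p from 0.084 to 0.98 in both reagents, and with the block neural ectoderm genes were called lower in MO2+MO3 (0.042, against 0.084). That call was lost with the block and an estimated correlation (camera adjusted p = 0.56).

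Over all 32539 probe sets the changes of the reagents correlated at r = 0.424 at stage 8 (Spearman 0.427) and r = 0.626 at stage 10.5 (Spearman 0.614). These are correlations across probe sets, which are not independent replicates, and both reagents share the CoMO arrays. Simulated unchanged groups gave r = 0.5 and 0.497. The covariance was 0.0115 at stage 8, against 0.0453 simulated without the replicate pairing and 0.0069 with it, and 0.0627 at stage 10.5, against 0.0449 and 0.00684. Within replicate pairs r was 0.278 and 0.535 at stage 8 and 0.632 and 0.6 at stage 10.5. Without MO1 replicate 1 at stage 10.5 r was 0.39, and without CoMO replicate 1 it was 0.804.

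**Figure D3:**
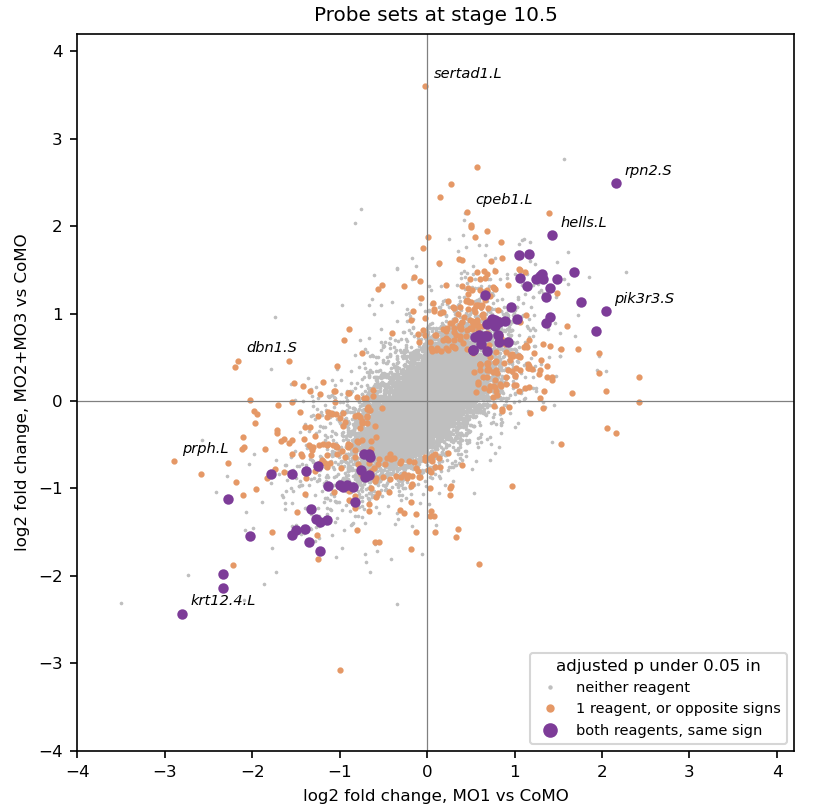
Log2 change at stage 10.5 against CoMO in MO1 (x axis) and in MO2+MO3 (y axis) for each probe set, with colour for an adjusted p under 0.05 without the replicate block in both reagents with the same sign, in 1 reagent or with opposite signs, or in neither. The 70 shared calls lie in the upper right and the lower left, with *rpn2.S* and *krt12.4.L* at their ends, and *sertad1.L* and *dbn1.S* lie away from the diagonal.

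Between the reagents at stage 10.5, 4 named genes were lower in MO1 than in MO2+MO3: sertad1.L at -3.62 ± 0.34 (adjusted p = 0.0069), dbn1.S at -2.62 ± 0.12 (0.00053), tmem181.L at -2.21 ± 0.36 (0.048) and the lipid droplet gene plin3.S at -2.04 ± 0.19 (0.0069). In MO1, sertad1.L and this probe set of tmem181.L reached the range of the negative controls, so these sizes are lower bounds, and the mean difference over the 7 probe sets of tmem181.L was -0.94. The genes agap1.L, sag.L and caprin2.L were higher in MO1 by 2.02 ± 0.15, 1.90 ± 0.27 and 1.90 ± 0.25 (0.0025, 0.031 and 0.024), for sag.L a lower bound, since its MO2+MO3 arrays reached that range. The palmitoyltransferase gene zdhhc20.L rose by 0.97 in MO1 and fell by 0.97 in MO2+MO3 (0.048 and 0.049), a difference of 1.93 ± 0.17 (0.0069). With the block prph.L was also lower in MO1, at -2.22 ± 0.15 (0.00022, against 0.065 without it). In all, 179 probe sets differed (83 higher, 96 lower in MO1), and 3171 with the block. Leaving out 1 of the 4 arrays without the block gave 12 to 33.

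A change of a reagent's effect between the stages was called for few genes without the block. For MO1 the change at stage 10.5 exceeded that at stage 8 by 1.92 ± 0.20 for pik3r3.S and 1.80 ± 0.18 for pik3r3.L (adjusted p = 0.046 each) and was below it for krt12.4.L, at -2.96 ± 0.19 (0.006). For MO2+MO3 it was below it for krt12.4.L, at -2.62 ± 0.19 (0.016), and for rcan1.L, at -1.62 ± 0.13 (0.02). At stage 8 krt12.4.L had a recovered median level between 1.1 and 2.1, in the range of the negative controls, so a fall could not be seen there and the test does not show that the reagents acted on it at stage 10.5 only. With the block, krt12.5.S at -3.49, krt12.4.S at -2.65, prph.L at -2.67, hprt1.L at 2.06 and dnajc9.L at 1.69 were added for MO1, and sertad1.L at 3.79, tmem181.L at 2.57, cpeb1.S at 2.14, cpeb1.L at 2.12, krt12.5.S at -2.27, krt12.4.S at -2.12 and gjb2.L at -1.87 for MO2+MO3 (adjusted p 0.00068 to 0.0084). Of these, krt12.5.S, krt12.4.S, prph.L and gjb2.L also reached the range of the negative controls at stage 8, where a fall could not be seen. All groups of sertad1.L at stage 8 and its CoMO arrays at stage 10.5 reached that range too, so its 3.79 is not an exact size. In counts, 7 probe sets had such a difference for MO1 (3 higher, 4 lower) and 3 for MO2+MO3 (0 higher, 3 lower), and 1354 and 1250 with the block. Leaving out 1 array of the test without the block gave 7 and 3 without CoMO replicate 1 of stage 10.5, and otherwise 0 to 2 for MO1 and 0 for MO2+MO3. The normal change between the stages in CoMO embryos was not analysed here, since centring removed it.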

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

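The tests of a changed effect between the stages were planned, and all tests of explanations in this part were chosen after the results were seen. The effect of a reagent differed between stage 8 and stage 10.5 by an interaction test for 7 probe sets with MO1 and 3 with MO2+MO3 in the fit without the replicate block. These counts did not hold when 1 array of the test was left out: in that fit they fell, except without CoMO replicate 1 of stage 10.5. Without the block, leaving out 1 array also puts the difference between the replicate numbers into the contrast. This alone can lower the counts, so the check does not decide whether the changes are real. The named ones were pik3r3.S (1.92 ± 0.20), pik3r3.L (1.80 ± 0.18) and krt12.4.L (-2.96 ± 0.19) for MO1, and krt12.4.L (-2.62 ± 0.19) and rcan1.L (-1.62 ± 0.13) for MO2+MO3. At stage 8 krt12.4.L lay in the range of the negative controls, between 1.1 and 2.1, so a fall could not be seen there. The other 4 for MO1 and 1 for MO2+MO3 have no gene in the annotation.

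The first pattern is that changes at stage 10.5 ran with the change between the stages seen in the targeted embryos themselves, since that of CoMO embryos was not analysed: of 1187 probe sets lower in both reagents with the block, 37.6% rose in recovered level class between the stages and 6.57% fell, and of 1428 higher ones 10.5% rose and 23.4% fell. Slower progress of the injected embryos could give this pattern, but the classes decide little: with narrower classes from all arrays of a stage, tried first, 677 rising probe sets had median changes of -0.36 (MO1) and -0.21 (MO2+MO3), while 226 falling ones, at 0.03 and 0.02, were not clearly above all others (0.02 and 0.00). With the wider classes used for the shares above, chosen after that and taken from the targeted embryos' arrays so that CoMO does not enter, 4729 rising probe sets stood at -0.04 and -0.04 and 2804 falling ones at 0.08 and 0.07, against 0.03 and 0.01 for 13222 level ones, so a delay stays open. The targeted arrays enter both these classes and the changes, so noise in them would raise the medians of rising probe sets and lower those of falling ones. The 15 epidermal genes that rise had means of -0.56 and -0.48, and 0 of 10000 random sets of rising genes, or 0.07% and 0.09% of sets matched on level class, were as low. The 15 hold both copies of krt70, dlx3, grhl3 and tfap2a, which the random sets did not mirror, so these shares can be too small. The epidermal list was taken up because it stood out among the lists at stage 10.5 in the same data. The random sets were not chosen that way, so the shares partly restate the choice and give no separate support. The changes of the 15 ran from -2.22 to 0.45 in MO1 and from -1.88 to 0.4 in MO2+MO3. The keratins krt12.4.L, krt12.4.S and krt12.5.S, whose targeted arrays reached the range of the negative controls, are not among the 15. The first test had been set to exclude a delay as the whole cause of the epidermal falls, a bound given up because centring hides how steeply a gene rises and a delay lowers steep genes most. A p53 response to the oligonucleotides is neither shown nor excluded by its list, whose mean changes were -0.09 ± 0.06 and 0.03 ± 0.04. Here ± is the standard error over the 29 genes of the list. It does not measure the spread between arrays, and the genes are not replicates.

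The second pattern is that changes at stage 8 recurred at stage 10.5: of the 40 probe sets called in MO1 with the block 92.5% kept their sign (95% exact interval 79.6 to 98.4%), and of the 46 called in MO2+MO3 100% (92.3 to 100%), against 57.3% and 58.7% of all probe sets. These shares argue against chance differences between replicates, since the replicates of the 2 stages deviate independently of each other. The intervals in this paragraph count probe sets as independent. Probe sets of the same gene, such as those of dbn1.S, move together on the same arrays, so the intervals can be too narrow. Loss of the common target predicts the same sign in the other reagent, which only 45% (29.3 to 61.5%) and 65.2% (49.8 to 78.6%) showed at stage 10.5. The upper bounds lie under 80%, a limit set after the shares were known, by a narrow margin for MO2+MO3. A wider interval could pass that limit, so the share of MO2+MO3 does not decide. Loss of the common target can also still hold for single genes such as rpn2.S. The sizes recurred too, with slopes of 0.87 (0.74 to 0.99) and 0.81 (0.72 to 0.90), which is what embryos of each injected group from their own clutch of eggs in both replicates might give, and equally an action of each oligonucleotide on other RNAs. These cannot be told apart, because no label gives the clutch.

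The third pattern is the difference between the reagents at stage 10.5, where 3171 probe sets differed with the block. A difference in strength alone would put the larger change in the same reagent, but it lay in MO1 for 50.7% (49 to 52.5%) of them, and 78 were called with opposite signs. That interval also counts probe sets as independent and can be too narrow. The fault of a single array is argued against by the correlation of the difference between the replicate pairs, r = 0.655 over all probe sets. Different actions of the oligonucleotides besides the common target, different doses and clutches stay open and were not tested. At least 1 technical explanation stays open for each of the 3 patterns, so none is called biological here.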

How the results depend on the processing

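Alternatives were planned, except those chosen after seeing the data: the block together with another choice, the recovered level, the variance trend on it, and 1 mean value per gene symbol or its probe set of highest recovered level. Counts below follow the order MO1, MO2+MO3, both reagents, mean of both, and MO1 against MO2+MO3, and where a setting is not named for a result its count stayed within 1.5 times of that reported. Each is a count of probe sets called with limma, and except where the construction of a setting shows it the cause of a change was not tested. Signal over background was judged only from the recovered level: of 75 named probe sets, 27 at stage 8 and 10 at stage 10.5 had a group whose lowest array may lie below 4, where the 6 TrpnX negative controls lie, which makes a change to or from it a lower bound.

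The replicate block gave 40, 46, 4, 17 and 124 at stage 8 and 5280, 5464, 2615, 6223 and 3171 at stage 10.5, and 1354 and 1250 for a change of the effect of MO1 and MO2+MO3 between the stages. It removes the large shared difference between replicates, which is what raised the counts. With the block and a 2-fold change the counts were 22, 19, 3, 4 and 37 at stage 8, 485, 438, 134, 318 and 308 at stage 10.5, and 404 and 342 between the stages. With the block and only the 6 arrays of a stage they were 14, 1, 1, 1 and 20 at stage 8 and 4351, 4482, 1987, 5465 and 2319 at stage 10.5. With the block and only probe sets at a recovered level of at least 4 they were 59, 71, 7, 27 and 191 at stage 8, 5817, 6008, 3093, 6699 and 3789 at stage 10.5, and 1730 and 1740 between the stages. With the block and 1 value per gene symbol, which tests fewer items, they were 33, 32, 5, 14 and 156 at stage 8, 2222, 2140, 1039, 2435 and 1544 at stage 10.5, and 662 and 625 between the stages. The block changed no call of a named gene from called to not called.

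Without the block, a second quantile normalization gave 152, 149, 38, 132 and 91 at stage 10.5. Calls between the stages for MO1 were then 1 higher and 4 lower, against 3 higher and 4 lower as reported. A 2-fold change left 166, 134, 30, 104 and 98 at stage 10.5. Only the 6 arrays of a stage, with 3 residual degrees of freedom, called 0 of the 2 probe sets in MO1 and 0 of the 2 between the reagents at stage 8, and 0, 0, 0, 0 and 0 at stage 10.5, although in the limma fit to all arrays 628 and 794 probe sets at stage 8 and 3535, 3698, 4011 and 2676 (MO1, MO2+MO3, mean, difference) at stage 10.5 had an unadjusted p under 0.05. At a recovered level of at least 4 the change between the stages was called for 2 and 1 probe sets, and with a variance trend on that level for 11 and 1. With 1 value per gene symbol 0 were called in MO1 and 0 between the reagents at stage 8, and 138, 124, 33, 139 and 81 at stage 10.5.

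Leaving out 1 array, with or without the block, gave 0 to 56, 0 to 40, 0 to 6, 0 to 32 and 0 to 69 calls at stage 8, 38 to 2676, 2 to 2849, 1 to 1496, 4 to 4842 and 12 to 1303 at stage 10.5, and 0 to 796 and 0 to 865 between the stages; the lone array of a group is assumed to vary like the others. With the block alone the ranges were 5 to 56, 1 to 40, 1 to 6, 1 to 32 and 28 to 69 at stage 8, 2037 to 2676, 2183 to 2849, 1087 to 1496, 2561 to 4842 and 873 to 1303 at stage 10.5, and 215 to 796 and 106 to 865 between the stages. The lowest of stage 8, 5 in MO1 and 1 each in MO2+MO3, both and the mean, came without CoMO replicate 2. Each array left out leaves 1 complete pair at its stage for its contrast. The low ends over all fits come from those without the block, where any 1 array left out of the contrast lowered the counts of stage 10.5 by more than 1.5 times: MO1 to 102 and 38 without CoMO replicates 1 and 2 and to 53 and 87 without MO1 replicates 1 and 2, and MO2+MO3 to 45 and 4 without those of CoMO and to 16 and 2 without its own; both reagents together then had 22, 3, 13, 20, 9 and 1 in that order of arrays. The correlation between the reagents ranged from 0.206 to 0.83 at stage 8 and from 0.39 to 0.804 at stage 10.5, highest without a CoMO array. Called lists in MO2+MO3 numbered 3 to 4 at stage 8, 3 without either CoMO array, and 3 to 7 at stage 10.5, the lowest at stage 10.5 without CoMO replicate 2. The median of ribosomal protein genes in MO1 ranged from -0.26 to 0.29 at stage 8 and from -0.29 to 0.04 at stage 10.5; it was reversed at 0.16 without CoMO replicate 2 and 0.29 without MO1 replicate 1 at stage 8, and at 0.04 without CoMO replicate 2 at stage 10.5. Over all list tests with 1 array left out 237 stayed on their side of the threshold, 25 lost their call, 7 gained one and 3 reversed.

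Of the 12 called lists of MO1 at stage 10.5, 1 remained called with an estimated correlation, and 0 of the 6 of MO2+MO3, 0 of the 3 of MO1 at stage 8 and 0 of the 5 of MO2+MO3 at stage 8 did. Fry called 1 and 1 at stage 10.5 and 0 and 0 at stage 8, and the block with an estimated correlation called 0, 0, 0 and 0. Over the 68 list tests, centring each array on its median changed 0, the block made 2 pass and 2 fail, and the probe set of highest recovered level made 2 fail. Over the named genes, the block made 160 of 424 tests pass and left 264 on the same side, array weights made 3 of 140 fail, the mean over all probe sets of a symbol 7, a second quantile normalization 8 with 1 passing, and the robust variance 0. In the tests with 1 array left out 1661 stayed on their side, 201 lost their call and 6 gained one, and 0 named genes reversed. Not run, since they need levels, were the filters at 5 and 7, the variance trend on the mean, the probe set with the highest mean and the contrast of CoMO embryos between the stages.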

Other observations

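The contrasts and lists in this part were planned, and the tests of recurring calls and of recovered level classes were chosen after the results were seen. Several members of the lists were called with the replicate block at stage 10.5. The pluripotency gene pou5f3.3.L rose by 1.14 in MO1 and 1.45 in MO2+MO3 (adjusted p = 0.001 and 0.00045) in the list of early zygotic genes, whose medians were -0.13 and -0.02. That list was fixed in advance, and whether the RNA of pou5f3.3.L is maternal or zygotic was not tested. The cell cycle regulator fzr1.L rose by 1.12 and 0.68 (0.00024 and 0.0018). In the p53 and stress list foxo3.L rose by 0.27 and 0.34 (0.03 and 0.013), while btg2.S, sat1.S and the apoptosis gene bax.S fell in MO1, with changes of -0.69, -0.82 and -0.50 (0.0048, 0.0021 and 0.014). Their differences of MO1 from MO2+MO3 were -0.61, -0.73 and -0.18 (0.011, 0.0052 and 0.32 with the block). None of these genes was called without the block (adjusted p = 0.079 to 1 over both reagents).

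With the block at stage 10.5, 3 genes of the endoplasmic reticulum chaperone list rose and 7 fell in MO1, and 1 rose and 7 fell in MO2+MO3. In the secretory list 5 rose and 10 fell in MO1, and 2 rose and 7 fell in MO2+MO3. Among them, herpud1.S and herpud1.L were lower in both reagents at stage 10.5 with the block, at -0.64 and -0.89 (adjusted p = 0.0074 and 0.002) and -0.76 and -0.47 (0.0033 and 0.024). Both derl1.L and derl2.L, which act in the degradation of misfolded proteins of the endoplasmic reticulum, fell in MO2+MO3, with changes of -0.97 and -0.87 (0.001 and 0.0012), and had changes of -0.01 and 0.03 in MO1 (0.95 and 0.86). The differences of MO1 from MO2+MO3 were 0.96 and 0.90 (0.0016 and 0.0015 with the block, 0.082 and 0.074 without it). The translocon gene ssr3.S and the oligosaccharyltransferase gene ostc.L were lower in both, at -0.44 and -0.63 (0.01 and 0.0024) and -0.60 and -0.45 (0.0018 and 0.0073). In MO1 pdia4.L fell, with a change of -0.74 (0.015), and kdelr1.L rose by 0.69 (0.0012), with changes of -0.51 and 0.09 in MO2+MO3 (0.064 and 0.53) and differences of MO1 from MO2+MO3 of -0.23 and 0.60 (0.42 and 0.0035 with the block). Without the block 0 of the genes named in this paragraph were called (adjusted p = 0.063 to 1).

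Of the 40 probe sets called in MO1 at stage 8 with the block, 34 were called again in MO1 at stage 10.5 with the same sign, and 7 in MO2+MO3. Of the 46 called in MO2+MO3 at stage 8, 41 were called again in MO2+MO3 at stage 10.5 with the same sign, and 11 in MO1. The 30 probe sets called lower in both reagents at stage 10.5 without the block held 18 that rise in level class between the stages in the targeted embryos and 2 that fall, and the 40 called higher held 5 and 6. Among all 32539 probe sets 4729 rise and 2804 fall. No uninjected embryos were among the samples, so changes shared by both reagents at both stages, such as those of rpn2.S and uqcrc1.L, were not separated from a change made by CoMO itself.

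The median and the mean of some lists that were not called pointed in opposite directions. At stage 10.5 these were the list of poly(A) tail control and mRNA decay, with medians of -0.03 and -0.02 and means of 0.02 and 0.05 in MO1 and MO2+MO3, and in MO2+MO3 neural ectoderm genes (median 0.05, mean -0.04) and FGF targets (0.01 and -0.09). At stage 8 they were mesoderm genes in MO1 (0.03 and -0.02) and, in MO2+MO3, the p53 and stress list (0.04 and -0.04) and maternal genes (-0.01 and 0.02). Their camera adjusted p lay between 0.66 and 0.98.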
